A study of Nicotiana benthamiana with 3 samples.

How the data were processed

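Expression was measured in leaves of Nicotiana benthamiana, a tobacco relative used for transient expression, on an oligonucleotide array of SuperSAGE tags. SuperSAGE is a sequencing method that represents each transcript by a short tag from near its 3′ end. Per the labels, total RNA labelled with biotin was hybridised, so each array has 1 colour. There were 3 arrays, with 1 array for each of the groups GFP (the control), NbCD1 and NbCD3, and groups were taken from the source name of each sample. The labels name no replicate arrays.

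The deposited table holds 1 normalized intensity per tag and array for 154 tags. The authors made these intensity values with RMA, per the submitters' processing notes, which name no version. The scanner, the array maker, the number of probes behind each tag, any filter and any background measurement are not given in the sources used here. The values are linear. All 462 of them have a log2 that lies within 1e-05 of a number with 3 decimals, so the table appears to be log2 output turned back to a linear scale. No background level, detection call or spot-level spread came with the table, so the number of arrays limits the precision and no error can be attached to a single tag.

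The names of the tags have the form NbCD1U20 or NbCD3D4. The letters U and D were read as tags selected as up or down in the SuperSAGE comparison of NbCD1 or NbCD3 with GFP. This reading follows the selection described for the array and is not spelled out in the sources used here. The table pairs no tag with a gene name or a sequence. The 13 keyword gene lists (defence, photosynthesis and others) fixed before the data were examined could therefore not be applied, and the 4 lists in the tag names were used in their place, a choice made after the names were seen.

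Each value was turned into log2 with no pseudocount and no filter, and differences of log2 values were taken between arrays. With 1 array per group there is no test across samples, and no p-value is given. The main result is the number of tags with a log2 difference of at least 1, which is 2-fold, in either direction. The tags named are the 2 largest increases and the 2 largest decreases of each comparison, a rule fixed before the data were examined. The median of a list was placed among the medians of 10000 random lists of the same size, matched in 5 strata of mean level over the arrays. For NbCD1 against GFP, this mean level included the NbCD3 values with the names as deposited. The placement describes these arrays only. Because both comparisons with GFP use the same GFP array, their correlation was set beside 10000 simulated sets of 3 unchanged arrays. Each simulated array had the same noise, the largest that the differences between the NbCD3 and NbCD1 arrays allow for these arrays under equal noise. These differences do not bound the noise of the GFP array, which was assumed to be the same. A noisier GFP array would raise the simulated overlap and correlation.

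The NbCD3 values were read in 2 ways. The first takes the tag names as deposited. The second, called NbCD3-first order, was added after the data were seen. It lists all names with U before D and by number, once with the NbCD1 lists before the NbCD3 lists and once with the NbCD3 lists before the NbCD1 lists, and moves each NbCD3 value from the name at its place in the first list to the name at that place in the second. The value deposited for NbCD1U1 thus becomes that of NbCD3U1. The second reading was found among 455 simple orders by its correlation with the GFP array.

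Alternatives fixed beforehand were centring each array on its median or its 75th percentile, quantile normalization of the 3 arrays, leaving out the tags whose mean over the arrays lay in the lowest 25%, thresholds of 1.5-fold and 4-fold, and a pseudocount of 1413 intensity units. The calculations used Python 3.11.15, numpy 2.4.6, pandas 2.3.3 and scipy 1.17.1. They were tested on simulated data for NbCD1 against GFP, with 40 tags among 154 given a 4-fold change and noise of 0.3 (SD, log2). Of these 40 tags, 40 were found past 2-fold, and none of the 114 unchanged tags was (0 tags). A planted NbCD3-first order was found by the search over orders. The noise was below the 0.87 of the simulated unchanged arrays in NbCD3-first order. The test thus checks the calculation and not how many of the reported tags are unchanged.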

Results

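The study asked which leaf transcripts change when NbCD1 or NbCD3 is overexpressed in N. benthamiana. NbCD1 encodes a class II ethylene-responsive element binding factor, a kind of transcriptional regulator. Leaves were infiltrated with Agrobacterium carrying NbCD1, NbCD3 or GFP (green fluorescent protein, the control) under a promoter system switched on by the glucocorticoid dexamethasone. Dexamethasone was given 2 days after infiltration and leaves were harvested 4 hours later. The tags on the array came from an earlier sequencing step, in which libraries of 10269 GFP tags and 10884 NbCD1 tags, and of 10063 GFP tags and 10677 NbCD3 tags, were compared. Tags differing by more than 4-fold were selected. Of the 154 tags on the array, 44 were named NbCD1 U, 39 NbCD1 D, 42 NbCD3 U and 29 NbCD3 D. These lists were chosen on leaves treated in the same way, so their direction on the arrays is not independent evidence where the array and the list concern the same overexpressed gene.

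Each group had 1 array. The median intensity was 4583 on the GFP array, 4327 on the NbCD1 array and 3997 on the NbCD3 array. Intensities ran from 32.6 to 31499 on the GFP array, from 31.6 to 32996 on the NbCD1 array and from 29.3 to 32339 on the NbCD3 array. No value below has a replicate, so the differences describe these arrays and cannot be set against a spread between leaves.

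The first comparison, NbCD1 against GFP, asked which selected tags differed in leaves overexpressing NbCD1. The NbCD1 U tags were mostly higher and the NbCD1 D tags mostly lower on the NbCD1 array. The largest increase was that of tag NbCD1U20, whose intensity was 104.9 on the GFP array and 26542 on the NbCD1 array, a log2 ratio of 7.98. Tag NbCD1U4 followed, at 159.5 and 1951, a log2 ratio of 3.61. The largest decreases were those of tag NbCD1D12, at 31499 on the GFP array and 118.9 on the NbCD1 array (log2 ratio -8.05), and tag NbCD1D14, at 5951 and 31.6 (log2 ratio -7.56). With the pseudocount, the log2 ratios were 4.20 for NbCD1U20, 1.10 for NbCD1U4, -4.43 for NbCD1D12 and -2.35 for NbCD1D14, and quantile normalization gave -8.91 for NbCD1D12. NbCD1D12 was the brightest of all tags on the GFP array, and NbCD1D14 was the dimmest on the NbCD1 array.

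Across all 154 tags, 47 differed by at least 2-fold between the NbCD1 and GFP arrays, 29 of them higher and 18 lower in NbCD1. At the 4-fold level by which tags had been selected, 15 were higher and 4 lower. The median log2 ratio of all tags was -0.23. The arrays correlated across tags with a Pearson r of 0.65 (Spearman 0.71), where tags are not independent replicates.

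Among the 44 NbCD1 U tags, 33 were higher on the NbCD1 array and 11 lower, and the median log2 ratio was 0.82. 18 of them were at least 2-fold higher, 11 at least 4-fold higher, and 0 at least 2-fold lower. Of the 39 NbCD1 D tags, 37 were lower, with a median log2 ratio of -0.56, but 29 of the 39 lay within 2-fold of GFP and 3 were at least 4-fold lower. The median of the NbCD1 U list lay above, and that of the NbCD1 D list below, those of all 10000 random lists matched on level.

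The lists selected in the NbCD3 experiment were also compared between the NbCD1 and GFP arrays. Of the 29 NbCD3 D tags, 27 were lower in NbCD1, with a median log2 ratio of -0.51, and 6 of these by at least 2-fold. Of the 42 NbCD3 U tags, 23 were higher and 19 lower, with a median log2 ratio of 0.14. 11 of them were at least 2-fold higher and 2 at least 2-fold lower. The medians lay at percentile 3.32 of the matched random lists for NbCD3 D and at percentile 99.0 for NbCD3 U. The random lists were drawn from tags that include the D lists, so a high rank among them does not show a rise. For NbCD3 U, the 95% interval of the median over tags ran from -0.14 to 0.43, so no direction is given for it.

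**Figure D1:**
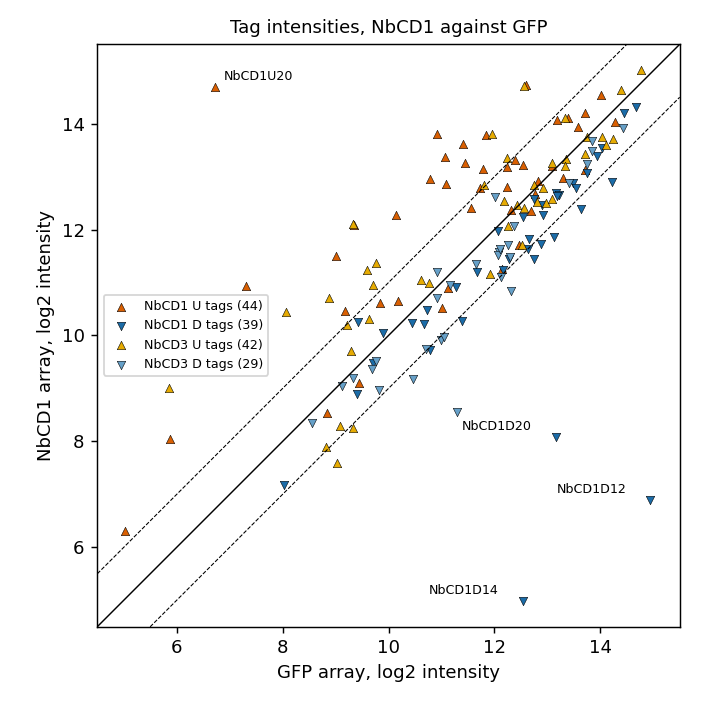
Log2 intensity of each of the 154 tags on the NbCD1 array (vertical axis) against the GFP array (horizontal axis), 1 array each. Each point is a tag, coloured by the list in its name; the solid line marks equal intensity and the dashed lines 2-fold differences. NbCD1U20 stands far above the line, NbCD1D12, NbCD1D14 and NbCD1D20 far below it, and 107 tags lie within the dashed lines.

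The second comparison, NbCD3 against GFP, depended on how the NbCD3 values were matched to tag names. With the names as deposited, the NbCD3 array correlated with the GFP array at r = -0.24 and with the NbCD1 array at r = -0.10. Read in NbCD3-first order, the same values gave r = 0.72 with GFP and r = 0.82 with NbCD1. Within the separate lists, r with GFP in that order was 0.91 for NbCD1 U, 0.56 for NbCD1 D, 0.80 for NbCD3 U and 0.81 for NbCD3 D. As deposited, r within these lists was -0.19, -0.39, -0.26 and 0.10. Both readings are given, but these correlations argue against the deposited names for the NbCD3 values, as set out further below. The directions of single tags on the NbCD3 array hold only for the reading named.

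With the names as deposited, 113 of 154 tags differed by at least 2-fold between the NbCD3 and GFP arrays, 58 higher and 55 lower in NbCD3. The split was 35 higher and 44 lower without the lowest 25% of tags, and 38 higher and 43 lower at 4-fold. Neither direction thus prevailed throughout. The largest increases were listed for NbCD3U23 (log2 ratio 8.01) and NbCD1U4 (7.66), and the largest decreases for NbCD3U38 (-7.38) and NbCD3U8 (-6.88). With the pseudocount these were 3.47, 4.42, -3.90 and -2.34, and quantile normalization gave -6.10 for NbCD3U8. Both tags with the largest decreases thus carried the name of the list selected as up in NbCD3. Of the 42 NbCD3 U tags, 22 were higher and 20 lower, with a median log2 ratio of 0.37, at percentile 65.7 of matched random lists. This median turned to -0.22 without the lowest 25% of tags, so no direction is given for it. Of the 29 NbCD3 D tags, 12 were higher and 17 lower, with a median of -0.73, at percentile 18.5. Of the 44 NbCD1 U tags, 31 were higher, with a median of 1.31, at percentile 99.9, and of the 39 NbCD1 D tags, 23 were lower, with a median of -1.35, at percentile 1.02. The latter median was -2.39 without the lowest 25% of tags. On the GFP array itself, the median log2 level was 11.7 for the NbCD1 U tags and 12.8 for the NbCD1 D tags. Since the NbCD3 values did not follow GFP in this reading, a list that is low on GFP tends to get a high ratio. These medians of the NbCD1 lists therefore do not show a response to NbCD3.

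In NbCD3-first order, 49 tags differed by at least 2-fold, 30 higher and 19 lower in NbCD3, and the median log2 ratio of all tags was -0.16. At 4-fold, 7 were higher and 9 lower, and at 1.5-fold, 41 were higher and 46 lower, so neither direction prevailed at every threshold. The NbCD3 U tags were then mostly higher and the NbCD3 D tags mostly lower on the NbCD3 array. The largest increase was that of tag NbCD3U1, at 647.2 on the GFP array and 23010 on the NbCD3 array (log2 ratio 5.15), followed by NbCD3U14, at 267.2 and 3816 (3.84). The largest decreases were those of NbCD1D12, at 43.5 on the NbCD3 array (-9.50), and NbCD1D14, at 29.3 (-7.67). With the pseudocount these were 3.57, 1.64, -4.50 and -2.35, and quantile normalization gave -8.91 for NbCD1D12. NbCD1D12 and NbCD1D14 are also the tags with the largest decreases on the NbCD1 array.

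Among the 42 NbCD3 U tags in this order, 31 were higher than in GFP and 11 lower, with a median log2 ratio of 0.58, and 16 were at least 2-fold higher. Of the 29 NbCD3 D tags, 28 were lower, with a median of -0.61, and 8 were at least 2-fold lower. The 44 NbCD1 U tags had a median of 0.32, with 29 higher, and the 39 NbCD1 D tags a median of -0.61, with 34 lower. The medians lay above all 10000 matched random lists for NbCD3 U, at percentile 0.42 for NbCD3 D, at percentile 99.9 for NbCD1 U, and below all 10000 for NbCD1 D.

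**Figure D2:**
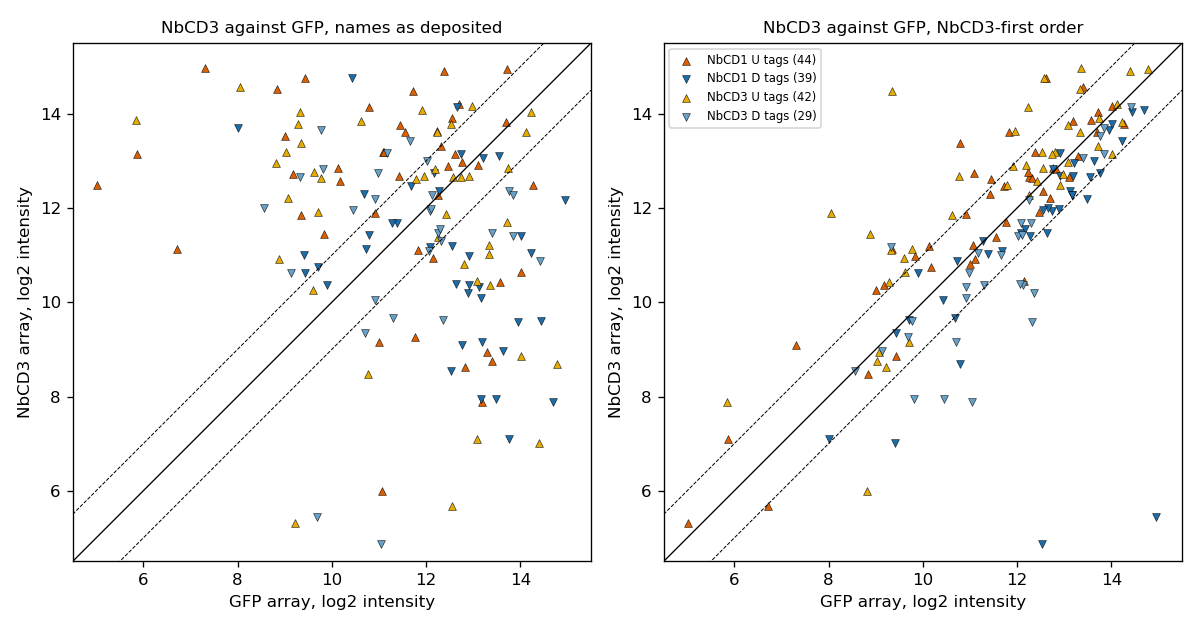
Log2 intensity of the 154 tags on the NbCD3 array (vertical axis) against the GFP array (horizontal axis), with tag names as deposited (left) and in NbCD3-first order (right). Each point is a tag coloured by the list in its name, the solid line marks equal intensity and the dashed lines 2-fold differences; r is -0.24 on the left and 0.72 on the right.

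The third comparison set the NbCD3 array directly against the NbCD1 array, without GFP. With the names as deposited, 108 tags differed by at least 2-fold, 55 higher and 53 lower in NbCD3. The largest increases were listed for NbCD1D7 (log2 ratio 6.52) and NbCD1U41 (6.18), and the largest decreases for NbCD3U38 (-7.62) and NbCD1U36 (-7.37). With the pseudocount these were 3.23, 2.26, -4.13 and -3.02, and quantile normalization gave 7.13 for NbCD1D7, -6.96 for NbCD3U38 and -6.44 for NbCD1U36.

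In NbCD3-first order, 34 tags differed by at least 2-fold, 10 higher and 24 lower in NbCD3. The split was 11 higher and 16 lower after quantile normalization and 6 higher and 6 lower with the pseudocount. NbCD3U1 was 75.1-fold higher in NbCD3, at 306.6 on the NbCD1 array and 23010 on the NbCD3 array, and NbCD1D20 was 18.3-fold higher, at 270.2 and 4939. NbCD1U20 was 521-fold lower in NbCD3, at 26542 and 50.9 (log2 ratio -9.03), and NbCD1U36 was 4.45-fold lower, at 10550 and 2371. With the pseudocount the log2 ratio was 3.83 for NbCD3U1, 1.92 for NbCD1D20 and -4.26 for NbCD1U20, and quantile normalization gave -8.12 for NbCD1U20. The NbCD1 U list was lower in NbCD3 than in NbCD1 for 32 of its 44 tags (median log2 ratio -0.21, percentile 0.685). Centring each array on its median brought this median to -0.094. The NbCD3 U list was higher for 29 of its 42 tags (median 0.32, above all 10000 matched random lists). The NbCD1 D list had a median of 0.04. The NbCD3 D list had a median of -0.091, which turned to 0.12 after quantile normalization and to 0.024 after centring each array on its median, so no direction is given for it.

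**Figure D3:**
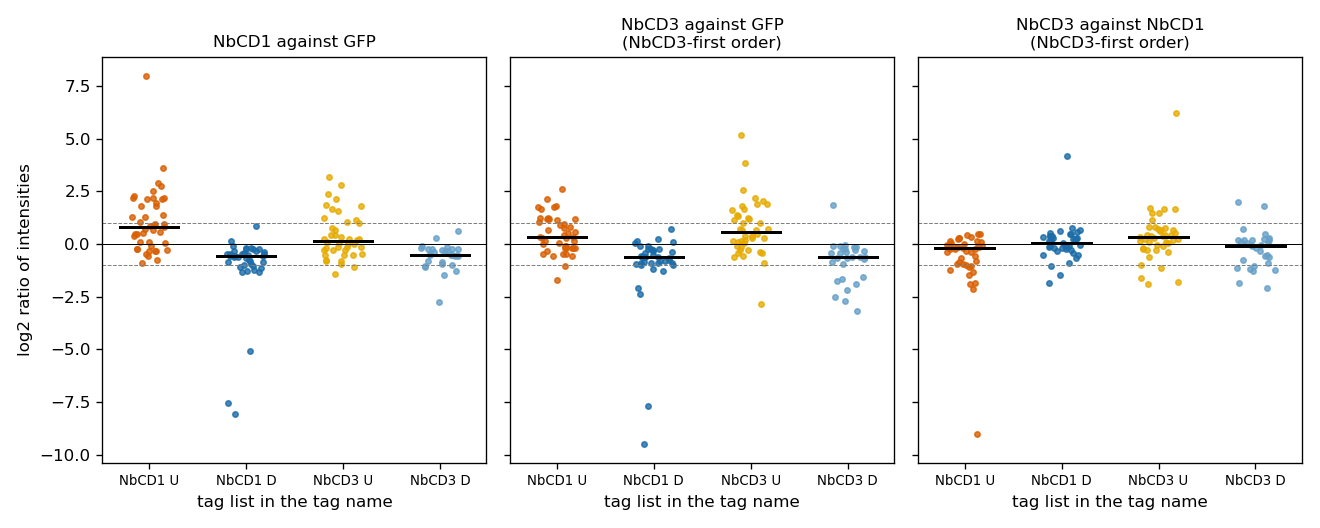
Log2 ratio of intensities (vertical axis) of each tag, grouped by the list in the tag name, for NbCD1 against GFP (left) and, in NbCD3-first order, for NbCD3 against GFP (middle) and NbCD3 against NbCD1 (right). Points are tags, black bars are list medians and dashed lines mark 2-fold. U lists have medians of 0.82 and 0.14 on the left and 0.32 and 0.58 in the middle, and the medians of both D lists lie below 0 in both.

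The comparisons of NbCD1 and of NbCD3 with GFP were then set against each other. In NbCD3-first order, 27 tags were past 2-fold in the same direction in both, 20 higher and 7 lower. Of the 20 higher tags, 11 were NbCD1 U and 9 NbCD3 U, and of the 7 lower tags, 3 were NbCD1 D and 4 NbCD3 D. Without tag sequences it is not known whether some transcripts were counted under more than 1 name. NbCD1U5 and NbCD3U18, for instance, had near-equal intensities on the GFP (6230 and 6047), NbCD1 (27044 and 27006) and NbCD3 arrays (27785 and 27746). With the arrays scaled as deposited, 2 tags went opposite ways past 2-fold: NbCD1U20, at log2 ratios of 7.98 in NbCD1 and -1.04 in NbCD3, and NbCD3U1, at -1.08 and 5.15. This count was 0 after centring on the median, after quantile normalization and with the pseudocount. Independent lists of these sizes would share 5.65 higher and 2.22 lower tags, and simulated unchanged arrays sharing 1 GFP array gave 14.3 in the same direction on average, with 22 at the upper end of their 95% range. With the names as deposited, 30 tags were shared, 20 higher and 10 lower, where independent lists would share 10.9 and 6.43. The simulation gave 65.0, but its noise of 2.13 (SD, log2) on each array was above the SD of 1.60 of the observed NbCD1 ratios. It is therefore no measure for this count.

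The log2 ratios of the comparisons with GFP correlated across tags at r = 0.69 in NbCD3-first order (Spearman 0.73) and at r = 0.37 as deposited (Spearman 0.31). Simulated unchanged arrays with the same GFP array gave a mean r of 0.49 in NbCD3-first order, with a 95% range from 0.24 to 0.72, and of 0.50 as deposited, with a range from 0.38 to 0.61 that lay above the observed r. The covariance in NbCD3-first order was 1.71, against 0.746 in the simulation, and as deposited it was 1.88, against 4.53. As deposited, the simulation gave each array equal noise of 2.13 (SD, log2). The observed log2 ratios had an SD of 1.60 for NbCD1 against GFP and 3.21 for NbCD3 against GFP. The arrays thus did not have that equal noise, and observed values below the simulated ones do not show less sharing than chance. Without NbCD1D12 and NbCD1D14, r in NbCD3-first order was 0.53 and the covariance 0.838, within the 95% range of the simulation without these tags, 0.260 to 1.47 with a mean of 0.754. With 1 GFP array the controls could not be split and the noise of GFP was assumed, so part or all of the overlap and of the correlation may come from the shared array.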

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

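The tests of other explanations in this part were chosen after the correlation of the NbCD3 array had been seen, except that the predictions for the search over simple orders and for the gap of the NbCD1 lists after moving the GFP and NbCD1 values were written before their results.

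Tags past 2-fold in opposite directions against GFP in NbCD1 and in NbCD3 numbered 6 with the names as deposited and 2 in NbCD3-first order. The latter passed 2-fold by little in their smaller ratios, -1.04 and -1.08 on the log2 scale, and their number was 0 after centring each array on its median, after quantile normalization or with the pseudocount. The count of 6 became 2 without the lowest 25% of tags and 2 with the pseudocount, and it was 19 at 1.5-fold and 1 at 4-fold. In NbCD3-first order the count was 1 without the lowest 25% of tags, 6 at 1.5-fold and 0 at 4-fold. The difference was not tested, since each group has 1 array. The 2 tags are NbCD1U20, near the top of the NbCD1 array, and NbCD3U1, near the top of the NbCD3 array.

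The NbCD3 array did not follow the other arrays across tags, at r = -0.24 with GFP, although GFP and NbCD1 correlated at 0.65. This r lies outside the central 95% of 10000 random orders of its values, -0.16 to 0.16, while its log2 interquartile range was 1.04 times and its median intensity 0.872 times that of GFP. Among 455 simple orders of the tag names, NbCD3-first order gave r = 0.72 with GFP, where the next best gave 0.35 and the highest of 1000 sets of as many random orders gave 0.35; its r with the NbCD1 array, which was not used to pick it, was 0.82, which argues against NbCD3 overexpression itself as the cause. Moving the GFP and NbCD1 values instead lowered the gap between the medians of NbCD1 U and NbCD1 D tags in NbCD1 against GFP to 0.31. It was 1.38 as deposited, which moving the NbCD3 values leaves unchanged. The NbCD3 lists then had a gap of 0.53 in NbCD3 against GFP, where moving the NbCD3 values gave 1.19. These gaps argue against moving the GFP and NbCD1 values, although the NbCD3 lists in NbCD1 against GFP barely differed (0.65, and 0.68 after it). The gap alone does not favour NbCD3-first order over the deposited names. For NbCD3 against GFP it was 1.10 as deposited for the NbCD3 lists and, for the NbCD1 lists, fell from 2.66 to 0.93. The ratios also spread less, at an SD of 1.54 against 3.21 as deposited. Directions of the NbCD3 lists, which were not used to pick the order, did favour it. NbCD3 U tags higher than GFP were 22 of 42 as deposited and 31 in that order. NbCD3 D tags lower were 17 of 29 and 28. For the NbCD1 lists, U tags higher went from 31 to 29 of 44 and D tags lower from 23 to 34 of 39. The correlations over all tags thus argue against the deposited names for the NbCD3 values. A candidate explanation is that the NbCD3 values were listed with the NbCD3 tags first and paired with a name list that began with the NbCD1 tags. Only the original array file could settle how this arose.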

How the results depend on the processing

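No paired analysis was possible because each group has 1 array. Centring on the median or the 75th percentile and quantile normalization left every count past 2-fold, shared count and correlation run under them within 1.5-fold, or for r within its 95% interval over tags, except that the 2 tags going opposite ways in NbCD3-first order became 0 with median centring and quantile normalization; centring on the median moved the median log2 ratio of NbCD3 against GFP from 0.14 to 0.34 as deposited and from -0.16 to 0.04 in NbCD3-first order. Reading NbCD3 in NbCD3-first order moved the counts from 113 to 49 (against GFP) and from 108 to 34 (against NbCD1) and r of the ratios from 0.37 to 0.69. It turned the log2 ratios of NbCD3U38 to 0.50 and NbCD3U8 to 0.29 (against GFP) and of NbCD1D7 to -0.076, NbCD1U41 to -0.98 and NbCD3U38 to 0.26 (against NbCD1). It turned the list medians against NbCD1 to -0.21 (NbCD1 U), 0.32 (NbCD3 U) and -0.091 (NbCD3 D); the first became -0.094 with median centring, and the last 0.024 with median centring and 0.12 with quantile normalization. The next values follow the order lowest 25% of tags left out, 1.5-fold, 4-fold, pseudocount. NbCD1 against GFP, 47 tags, became 30, 77, 19 and 24. In NbCD3-first order, NbCD3 against GFP, 49 tags, became 27, 87, 16 and 23, NbCD3 against NbCD1, 34 tags, became 17, 58, 5 and 12 (6 higher and 6 lower), and the 27 shared tags became 15, 57, 7 and 8. The 30 tags shared as deposited became 19, 49, 13 and 15. These follow from fewer tags, another threshold or folds shrunk by construction. In NbCD3-first order, r fell to 0.60 without the lowest 25% of tags and 0.53 without NbCD1D12 and NbCD1D14, so these tags carry part of it. Leaving out these 25% turned 2 list medians as deposited, NbCD3 U against GFP to -0.22 and NbCD1 D against NbCD1 to -1.37 (cause not tested). The rest of the list medians kept their sign under these alternatives, as did the named tags under all but the change of order, but the pseudocount brought the log2 ratios of nearly all named tags closer to 0, that of NbCD1U20 (NbCD1 against GFP) from 7.98 to 4.20 and that of NbCD1D14 from -7.56 to -2.35. No background signal was given, so folds of tags near the lowest intensities are the least certain.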

Other observations

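All tests in this part were chosen after the values had been seen. The NbCD3 values are in NbCD3-first order, except in the mean level on which random lists were matched, where the names are as deposited.

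NbCD1D12 and NbCD1U20 were near the top of 1 array and near the bottom of the others. NbCD1D12 was rank 154 of 154 on the GFP array and rank 3 from the lowest on both other arrays, and NbCD1U20 was rank 151 on the NbCD1 array and rank 4 from the lowest on both the GFP and NbCD3 arrays. These tags were picked by their NbCD1 and GFP values; on the NbCD3 array, which was not used to pick them, 2 of 2 values lay in the lowest 5%. Transcripts of the introduced genes, GFP for NbCD1D12 and NbCD1 for NbCD1U20, may give this pattern, but a bright spot on 1 array or a strong response of a plant gene would give the same values, and the tag sequences were not used here. NbCD1D14 was the dimmest tag on both the NbCD1 and NbCD3 arrays but only rank 94 on GFP, and NbCD3U1 was rank 147 on the NbCD3 array, rank 21 on GFP and rank 9 on NbCD1.

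The tags selected as down in the NbCD3 experiment were also mostly lower on the NbCD1 array, 27 of 29. A shift of the whole NbCD1 array by the median log2 ratio of all tags (-0.23) did not account for this alone. After subtracting it, 21 of 29 stayed below 0, where the 95th percentile of matched random lists was 19. All tags had been selected for a change, so this median is not an unchanged baseline, and a larger shift stays open. The chance level of these tags on the 1 GFP array stays open, because a high GFP value lowers both ratios and the direct difference between NbCD3 and NbCD1 for these tags, a median of -0.091, does not use GFP. A response shared by NbCD1 and NbCD3 may also give this pattern, and a second GFP array would be needed to tell it from that chance level. Even that array would not tell a shared response from a change in the GFP leaves, the control of both comparisons.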
